A study of Homo sapiens with 12 samples.

How the data were processed

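Primary human granulosa/lutein cells were cultured in medium with 10% serum, starved of serum for 1 h and treated for 12 h, per the labels' protocols. Samples were grouped by the treatment label into Control, hCG and hCG+RU486, with 4 libraries each, 12 in all. RNA libraries were made with a stranded poly(A) kit and sequenced from one end on a single lane, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20, STAR 2.7.10a, SAMtools, Salmon 1.10.1, limma, edgeR and the build GRCh38, without saying which tool made which value. The counting rule, the filter on genes and the model formula are not given in the sources used here.

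The file analysed is the authors' deposited table of results, with 18077 genes by Entrez identifier, 18049 of them with a symbol, and coordinates on GRCh38. Per the file headers, it holds signed fold changes with raw and adjusted p-values for 3 comparisons, an overall F statistic with its p-values, a mean expression on a log2 scale, an assignment to modules and gene ontology terms. The p-value columns and the fold ratio columns are the authors' own. The mean log2 expression is the authors' value pooled over their libraries, and it ranges from -3.24 to 13.03. The overall F score is likewise deposited by the authors. The table has 0 columns of values per sample, so depth per library, spread between libraries and libraries standing apart could not be examined.

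From these columns the following was computed. Signed fold changes were put on the log2 scale. The overall p-values follow an F distribution with 6 and 21.923 degrees of freedom, found by solving for the denominator over a sample of genes for each of 10 numerators. A t distribution with 21.923 degrees of freedom turned the authors' p-values into a standard error per gene, which was equal in the 3 comparisons to within a ratio of 1.00028. The log2 fold changes of the 3 comparisons added up to within 1.92e-06, and Benjamini-Hochberg adjustment of the raw p-values over 18077 genes differed from the authors' adjusted values by at most 1.89e-07. The median standard error was 0.25, or 0.41 for the genes with a mean log2 expression under 1 and 0.16 for those at 5 or more, so low genes need larger changes to pass. Confidence intervals are at 95%.

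The tests planned before the data were examined were count or log2 models on the 12 libraries. They could not be run on a table without values per library, so the authors' two-sided adjusted p-values at a threshold of 0.05 took their place. The part of the overall F beyond the 3 groups was obtained by subtracting their share and tested with 4 numerator degrees of freedom. A test against a fold of 1.2 used the same standard errors.

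Gene lists (38) were fixed before the data were examined, of which 35 had the 5 listed members needed for limma's camera test, here in the form that takes one statistic per gene, with a preset correlation of 0.01. A correlation could not be estimated without values per library, so calls were repeated with a preset correlation of 0.05 and with ranks. No mitochondrially encoded mRNA was listed. Symbols were matched directly or through the Entrez identifier. Gene ontology terms of 10 to 500 listed genes (1349 terms) were taken from the deposited table and tested with the same settings.

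Named genes were chosen by a rule written before the data were examined. It took PGR and SOX9, the 10 largest increases and 10 largest decreases for hCG and for RU486, the 5 largest each way against Control, the 10 and 5 genes moved back the most, and up to 4 members with the smallest adjusted p from each list with up to 2 that went the other way. Clone, antisense and unnamed loci were left out. The rule also asked for libraries without overlap and a mean log2 value of 1 in the higher group. Neither can be seen here, and for genes ranked by the size of their change an overall mean log2 expression of at least 1 was used, which leaves out some genes with larger fold changes and a low overall mean. Members named from the lists had no minimum. XIST and Y-linked genes are not reported.

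Comparisons sharing the hCG libraries were set against 100 simulated draws without effect, and their intervals came from 1000 bootstrap draws over genes. Intervals of list medians came from bootstrap draws over the genes of the list. Scripts were tested on simulated data for 18077 genes with 200 changed, in 7 groups of 4 libraries. For hCG against Control, 10.4% of 1.5-fold, 49.3% of 2-fold and 84.8% of 4-fold changes were recovered with 7 false calls, and 24 of 33 simulated 4-fold changes that moved back were found. In the data 18.8% of genes were called for hCG, a far larger share than was simulated. These rates are therefore not the sensitivity of the calls reported here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

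Some single genes are not reported here, and the lists that hold them were tested whole.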

Results

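Messenger RNA was measured by stranded poly(A) sequencing in primary human granulosa/lutein cells, the steroid-producing cells that line the ovarian follicle and form the corpus luteum. The cells came from oocyte retrievals and were cultured for 6 days before treatment. They then received no hormone (Control), human chorionic gonadotropin (hCG, a ligand of the luteinizing hormone receptor that stands in for the ovulatory surge), or hCG with RU486 (mifepristone, an antagonist of the progesterone and glucocorticoid receptors) for 12 h. Each of the 3 groups had 4 libraries, and the labels do not say whether these came from separate donors or cultures, so how far the p-values cover differences between donors is unknown. The values come from the authors' deposited table of comparisons, which lists 18077 genes with a signed fold change and p-values per comparison and gives no value per library. Sequencing depth per library is therefore unknown. Log2 fold changes below are the authors' fold changes on the log2 scale, and each ± is the standard error that the authors' p-values imply, with a median over all genes of 0.25.

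The comparison of hCG with Control asks what the ovulatory stimulus changed within 12 h. In the authors' deposited table, PGR, the progesterone receptor (Entrez Gene 5241, chromosome 11 from 101029624 to 101130681, GRCh38), was higher with hCG by 1.90 ± 0.52 on the log2 scale. SOX9, a transcription factor of gonad and cartilage development (Entrez Gene 6662, chromosome 17 from 72121020 to 72126420), was higher by 2.80 ± 0.33. Their adjusted p-values in the authors' deposited table were 0.014 for PGR and 6.3e-06 for SOX9. Among the genes named by a rule of size, the increases were led by HAL, which encodes histidine ammonia-lyase, at 7.22 ± 0.98, the matrix gene FREM2 at 6.43 ± 0.57, the neuropeptide precursor NTS at 6.23 ± 0.34 and MRO at 6.13 ± 0.97. Decreases included RRAD, a small GTPase gene, at -3.62 ± 0.49, the matrix glycoprotein gene THBS1 at -3.51 ± 0.58 and the transcription factor SOX4 at -2.98 ± 0.55. In total, 3406 genes passed an adjusted p of 0.05 in the authors' deposited table, 1979 of them higher and 1427 lower with hCG. Requiring a 2-fold change left 1683 genes, and a test against a fold of 1.2 left 1421.

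Genes of cholesterol synthesis and uptake rose together with hCG in the authors' deposited table. Of 28 listed members 22 rose and 1 fell, or 23 and 1 when adjusted over the list alone. The synthase gene HMGCS1 rose by 2.61 ± 0.35, whereas the sterol carrier gene STARD5 fell by 1.01 ± 0.23. The camera test of limma, which compares a list with all other genes, gave an adjusted p of 9.0e-17 for this list. Of 33 lipid droplet and fatty acid genes 14 rose and 1 fell (15 and 1 when adjusted over the list alone, camera adjusted p 2.0e-05), among them ELOVL5, a fatty acid elongase gene, at 2.31 ± 0.29. The steroidogenesis list had 7 higher and 2 lower members of 26 (9 and 3 when adjusted over the list alone), and camera did not call it (adjusted p 0.062). Its changed members included STAR, which moves cholesterol into mitochondria, at 1.94 ± 0.41, and CYP19A1, which encodes aromatase, at 2.00 ± 0.61. HSD3B1 and HSD3B2 are near-identical copies and their values of 0.40 ± 0.82 and 1.12 ± 0.50 are uncertain.

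The ovulatory mediator list had 10 members higher and 1 lower of 24 with hCG in the authors' deposited table (12 and 1 when adjusted over the list alone, camera adjusted p 4.5e-07). The EGF-like growth factor genes EREG and AREG rose by 4.66 ± 0.45 and 3.34 ± 0.51, the prostaglandin E synthase gene PTGES rose by 3.44 ± 0.38, and the endothelin gene EDN2 fell by 2.36 ± 0.70. Of 23 glucocorticoid receptor targets 11 rose and 0 fell (13 and 0 when adjusted over the list alone, camera adjusted p 8.2e-08), including CRISPLD2 at 3.86 ± 0.57 and FKBP5, a co-chaperone of steroid receptors, at 2.79 ± 0.27. Of 25 reported progesterone receptor targets 10 rose and 2 fell (12 and 3 when adjusted over the list alone, camera adjusted p 9.9e-05), and this list shares 4 genes with the former. The hypoxia list had 15 higher and 2 lower of 25 (17 and 2 when adjusted over the list alone, camera adjusted p 3.4e-06), with LDHA, a lactate dehydrogenase gene, at 1.41 ± 0.24 and the peptide hormone gene ADM at -0.96 ± 0.21. Of 9 metallothionein genes, which encode metal-binding proteins, 7 rose (7 when adjusted over the list alone, camera adjusted p 1.1e-06). MT1A rose by 5.40 ± 0.73, although members of this family are similar in sequence and their single values are uncertain. Camera also called the unfolded protein and heat shock list (6 higher of 21), the cAMP feedback list (6 of 32), the circadian clock list (6 higher and 1 lower of 18) and the luteal identity list (7 higher and 1 lower of 14), with adjusted p of 0.00061, 0.0016, 0.0043 and 0.0052. When adjusted over the list alone, these had 13 higher, 6 higher, 8 higher with 1 lower, and 9 higher with 2 lower. The circadian call was lost when ranks replaced the statistics (adjusted p = 0.055).

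Markers of other cell types were listed beside these groups. Theca and stromal markers had 1 higher and 3 lower of 15 with hCG (1 and 4 when adjusted over the list alone, camera adjusted p 0.33). Lymphocyte markers had 1 higher of 5 with hCG (2 when adjusted over the list alone, camera adjusted p 0.28). Of 19 macrophage and neutrophil markers 0 passed an adjusted p of 0.05 in any of the 3 comparisons in the authors' deposited table, and at an unadjusted p under 0.05 there were 1 with hCG, 0 with RU486 and 4 for hCG+RU486 against Control. Of 13 epithelial markers 1 rose and 2 fell with hCG, the latter being the keratin genes KRT18 at -1.78 ± 0.36 and KRT8 at -1.42 ± 0.32, and camera did not call the list (adjusted p 0.17). Of 9 endothelial markers 1 rose, VWF at 2.53 ± 0.62, and 1 fell, CLDN5 at -2.69 ± 0.74 (2 and 1 when adjusted over the list alone). Of 18 granulosa identity genes 3 rose and 4 fell (3 and 6 when adjusted over the list alone), with the activin-binding protein gene FST at 2.28 ± 0.29 and NR5A1, a regulator of steroidogenic genes, at -0.68 ± 0.13. Among 18 housekeeping genes 1 rose and 2 fell (3 and 3 when adjusted over the list alone), including ACTB at -0.61 ± 0.19. Of 15 genes known to respond to the stress of tissue dissociation 2 rose and 0 fell with hCG (4 and 0 when adjusted over the list alone), among them FOS at 3.07 ± 0.46. Camera did not call this list (adjusted p 0.053) but did with ranks (adjusted p = 0.030).

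The comparison of hCG+RU486 with hCG asks which transcripts changed when RU486 was added. None of the labelled groups was given RU486 alone, so a change need not pass through the receptors that it blocks. In the authors' deposited table, SOX9 fell with RU486 by 2.06 ± 0.33 on the log2 scale (adjusted p 0.00024). PGR had a value of -0.16 ± 0.52 and did not pass the test (adjusted p 0.89 in the authors' deposited table). The decreases named by the rule were led by SLCO2A1, which encodes the prostaglandin transporter, at -4.65 ± 0.76, CRISPLD2 at -4.20 ± 0.57 and the heparan sulfate sulfotransferase gene HS3ST1 at -4.08 ± 0.64, and included ZBTB16 at -3.75 ± 0.67 and FKBP5 at -3.59 ± 0.27. Increases were led by the sodium channel gene SCN4A at 5.10 ± 0.45, INHBE at 4.92 ± 0.70 and CHAC1, a glutathione-degrading enzyme gene, at 4.42 ± 0.62, and included IGFBP1, which encodes an insulin-like growth factor binding protein, at 4.03 ± 0.56. The authors' deposited table held 1798 genes past an adjusted p of 0.05, with 873 higher and 925 lower. A 2-fold requirement left 934 genes and a test against a fold of 1.2 left 721.

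Part of the ovulatory mediator list fell when RU486 accompanied hCG. Of 24 members in the authors' deposited table, 7 fell and 1 rose (8 and 1 when adjusted over the list alone, camera adjusted p 0.00095). HAS2, a hyaluronan synthase gene, fell by 3.13 ± 0.69, the protease gene ADAMTS9 by 2.65 ± 0.39, EREG by 2.10 ± 0.45 and the proteoglycan gene VCAN by 1.96 ± 0.48, whereas PPARG rose by 0.60 ± 0.19. Of 23 genes of prostaglandin synthesis, transport and reception 5 fell and 0 rose, as they did when adjusted over the list alone (camera adjusted p 0.0095, and adjusted p = 0.089 with a preset correlation of 0.05). They were SLCO2A1, PTGES at -2.40 ± 0.38, the receptor gene PTGER2 at -1.71 ± 0.46, the phospholipase gene PLA2G4A at -1.48 ± 0.32 and the transporter gene ABCC4 at -0.75 ± 0.22. Of 23 glucocorticoid receptor targets 8 fell and 0 rose (8 and 1 when adjusted over the list alone, camera adjusted p 1.3e-06), with PER1, a clock gene, at -2.25 ± 0.34 and GADD45B at -2.27 ± 0.38. Of 25 reported progesterone receptor targets 6 fell and 1 rose (8 and 2 when adjusted over the list alone, camera adjusted p 0.00065, and adjusted p = 0.082 with ranks). Of these targets, the 21 outside the glucocorticoid list had 3 lower and 1 higher. Of 18 SOX9 targets known from cartilage and gonad 0 passed in the authors' deposited table, also when adjusted over the list alone, with a median log2 fold change of -0.15. At an unadjusted p under 0.05 there were 2.

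Part of the stress-response list rose with RU486. In the authors' deposited table, 9 of 21 unfolded protein and heat shock genes rose and 0 fell (10 and 0 when adjusted over the list alone, camera adjusted p 6.6e-07). The median of the list was 0.06 and its mean 0.99, and with ranks camera no longer called it (adjusted p = 0.11). The risen members included TRIB3 at 3.44 ± 0.40, DDIT3, which encodes the transcription factor CHOP, at 3.41 ± 0.36, the asparagine synthetase gene ASNS at 3.16 ± 0.34, ATF4 at 1.57 ± 0.18 and the chaperone gene HSPA5 at 1.18 ± 0.27. Of 9 metallothioneins 5 rose and 0 fell relative to hCG alone (6 higher and 1 lower when adjusted over the list alone, camera adjusted p 0.00049). Of 23 apoptosis and survival genes 5 rose and 1 fell (6 and 3 when adjusted over the list alone, camera adjusted p 0.017). This camera call was lost with a preset correlation of 0.05 (adjusted p = 0.12) and with ranks (adjusted p = 0.11). PMAIP1, a pro-apoptotic BCL2 family gene, rose by 2.82 ± 0.32, and FAS, which encodes a death receptor, fell by 0.75 ± 0.23. Of 32 cell cycle genes 6 fell and 0 rose (7 and 1 when adjusted over the list alone, camera adjusted p 0.00095), among them CCNE2 at -1.98 ± 0.47, TYMS at -1.45 ± 0.33 and MCM4 at -1.08 ± 0.22.

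Few sterol genes passed the test between these groups. By the authors' deposited table, 1 of 28 cholesterol genes fell with RU486, HSD17B7 at -0.77 ± 0.24 (0 when adjusted over the list alone), and camera did not call the list (adjusted p 0.15). HMGCS1 had a value of -0.23 ± 0.35 and STAR of 0.21 ± 0.41. A value that misses the threshold does not show that the groups were alike.

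**Figure D1:**
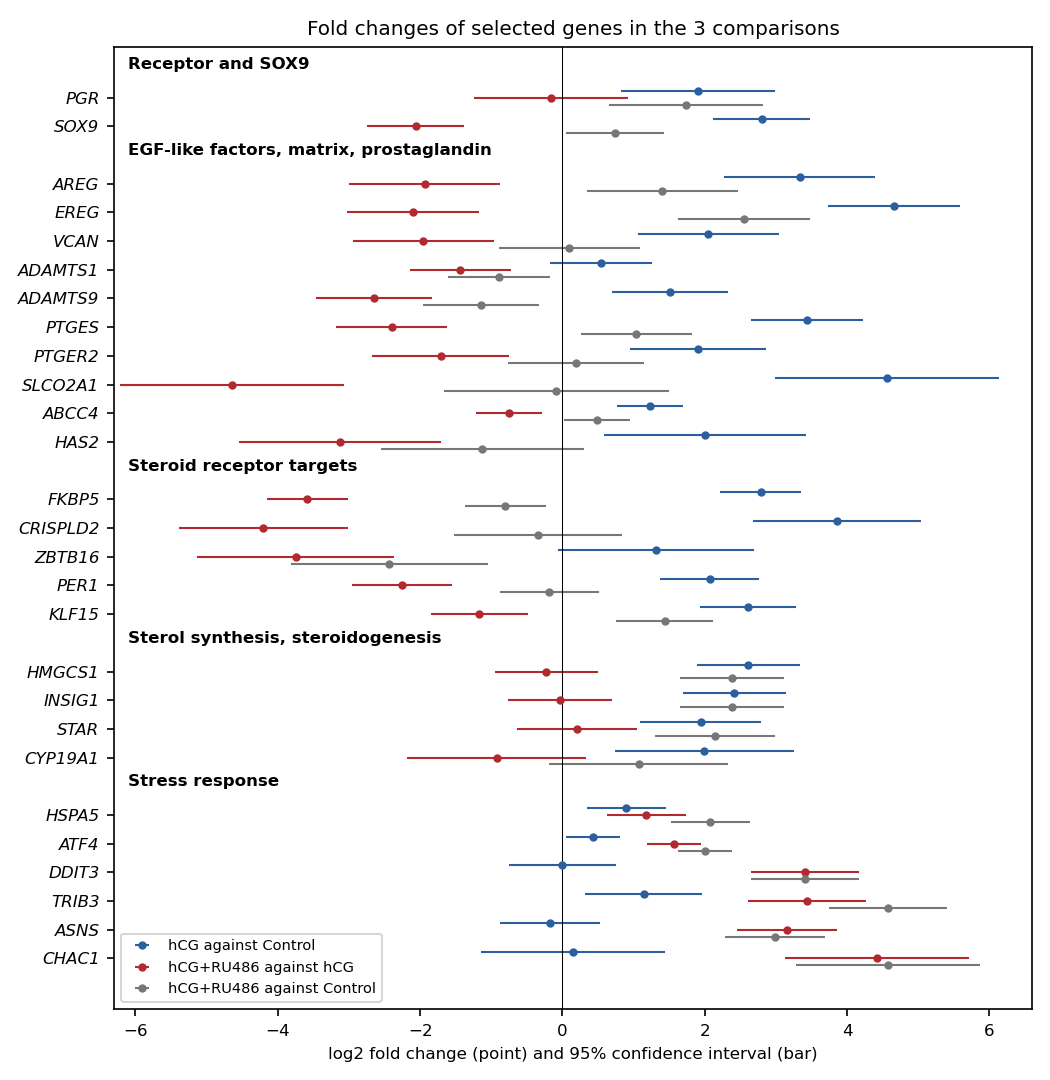
Log2 fold changes of selected genes (points) with 95% confidence intervals (bars), computed from the authors' deposited table, for hCG against Control (blue), hCG+RU486 against hCG (red) and hCG+RU486 against Control (grey). SOX9 lies at 2.80 with hCG and at -2.06 with RU486, whereas HMGCS1 lies at 2.61 and -0.23.

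The comparison of hCG+RU486 with Control shows what differed from untreated cells when both compounds were present. The authors' deposited table had 2956 genes past an adjusted p of 0.05, 1663 higher and 1293 lower, with 1475 at 2-fold or more and 1215 in a test against a fold of 1.2. PGR was higher than in Control by 1.74 ± 0.52, and SOX9 had a value of 0.74 ± 0.33 (adjusted p 0.13 in the authors' deposited table). IGFBP1 was higher by 6.38 ± 0.56, and OXTR, the oxytocin receptor gene, was lower at -4.18 ± 0.64. Of 9 metallothioneins 8 were higher (8 when adjusted over the list alone, camera adjusted p 2.2e-18), and of 28 cholesterol genes 21 were higher and 1 lower (23 and 2 when adjusted over the list alone, camera adjusted p 3.5e-12). Of 33 lipid droplet and fatty acid genes 16 were higher and 0 lower (19 and 0 when adjusted over the list alone, camera adjusted p 5.2e-08), and of 21 unfolded protein and heat shock genes 11 were higher and 0 lower (13 and 0 when adjusted over the list alone, camera adjusted p 5.2e-18). Of 32 cell cycle genes 11 were lower and 3 higher (13 and 3 when adjusted over the list alone, camera adjusted p 0.00036). Of 13 epithelial markers 5 were lower (7 when adjusted over the list alone, camera adjusted p 0.00063), including KRT19 at -2.15 ± 0.48. Of 15 theca and stromal markers 2 were lower and 1 higher (5 and 1 when adjusted over the list alone), with a median log2 fold change of -0.71. Camera gave this list an adjusted p of 0.040, which was 0.14 with a preset correlation of 0.05 and 0.0042 with ranks. Of 25 hypoxia genes 8 were higher and 1 lower (9 and 1 when adjusted over the list alone). Their camera adjusted p was 0.014, or 0.12 with a preset correlation of 0.05 and 0.0048 with ranks. The macrophage and neutrophil list had 0 of 19 members past the threshold, yet all 19 values lay below 0, with a median log2 fold change of -0.52 and a highest value of -0.028. Camera called this list lower with an adjusted p of 0.043, or 0.0042 with ranks, but not with a preset correlation of 0.05 (adjusted p = 0.18).

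**Figure D2:**
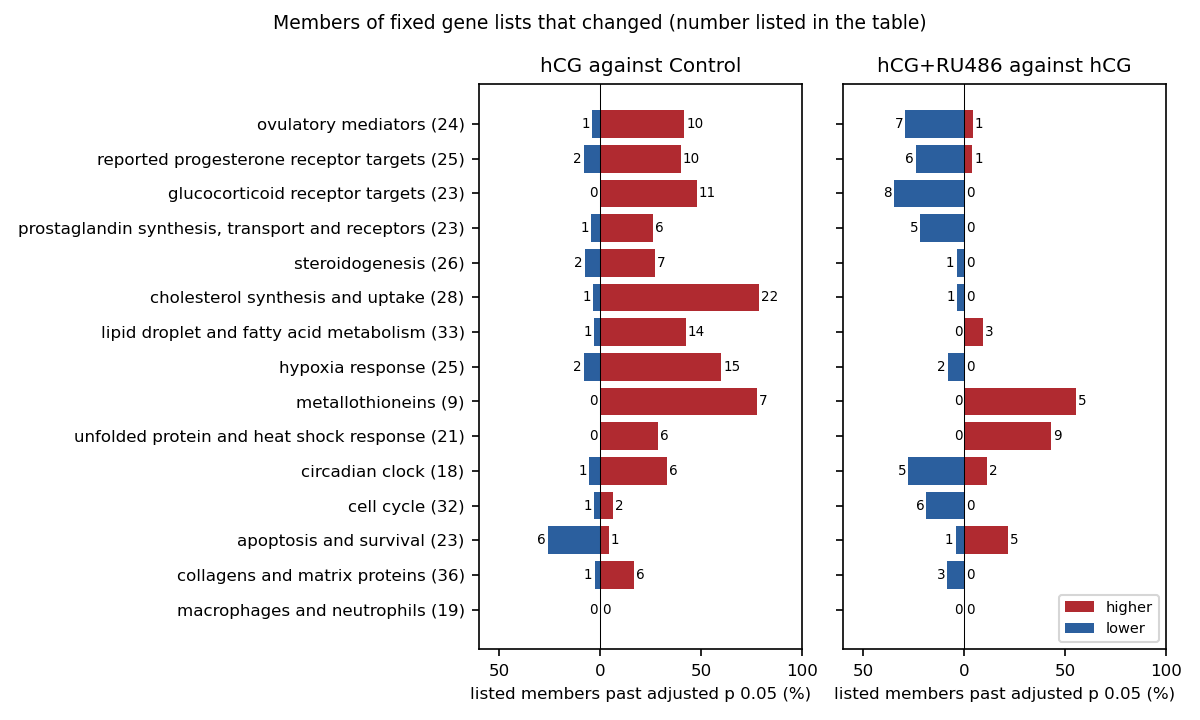
Share of listed members of 15 fixed gene lists past an adjusted p of 0.05 in the authors' deposited table, higher (red, right) or lower (blue, left), with the number of genes at each bar and the number listed in brackets. Of 28 cholesterol genes 22 were higher with hCG and 1 was lower with RU486.

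Genes changed by hCG were compared with those changed by adding RU486. By the authors' deposited table, 558 of the 1979 genes raised by hCG were lower with RU486, or 28.2%, where independent lists would share 101. Of these, 511 did not pass the test against Control, 38 stayed above it and 9 lay below it. Of the 1427 genes lowered by hCG 199 were higher with RU486, or 13.9%, where independent lists would share 68.9. The 757 genes that moved back included RGS2, a regulator of G protein signalling, at 3.28 ± 0.49 with hCG and -3.09 ± 0.49 with RU486, ID4 at 5.03 ± 0.52 and -3.04 ± 0.52, and DACT1 at -2.48 ± 0.42 and 2.22 ± 0.42. A further 636 genes higher with RU486 had no call for hCG, which is 72.9% of the genes that RU486 raised, and 361 genes lower with RU486 had no call for hCG. At 2-fold in both comparisons 394 genes moved back, and 280 did in a test against a fold of 1.2.

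Both comparisons contain the hCG libraries, which pushes their fold changes in opposite directions with no effect at all. Across the 18077 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table had a Pearson r of -0.474 and a Spearman rho of -0.420. Simulated groups without any effect gave -0.499 and -0.462. The covariance was -0.225 (95% bootstrap interval -0.240 to -0.210) against -0.056 in the simulation. An unadjusted p under 0.05 in both comparisons with opposite signs was found for 1902 genes, where the simulation had a mean of 190.79. At that p 5771 genes passed for hCG and 4316 for RU486. Real but unrelated effects, which the simulation did not hold, also raise such an overlap, so its excess does not measure how many genes moved back. Splitting the hCG libraries between the comparisons was not possible without values per library.

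**Figure D3:**
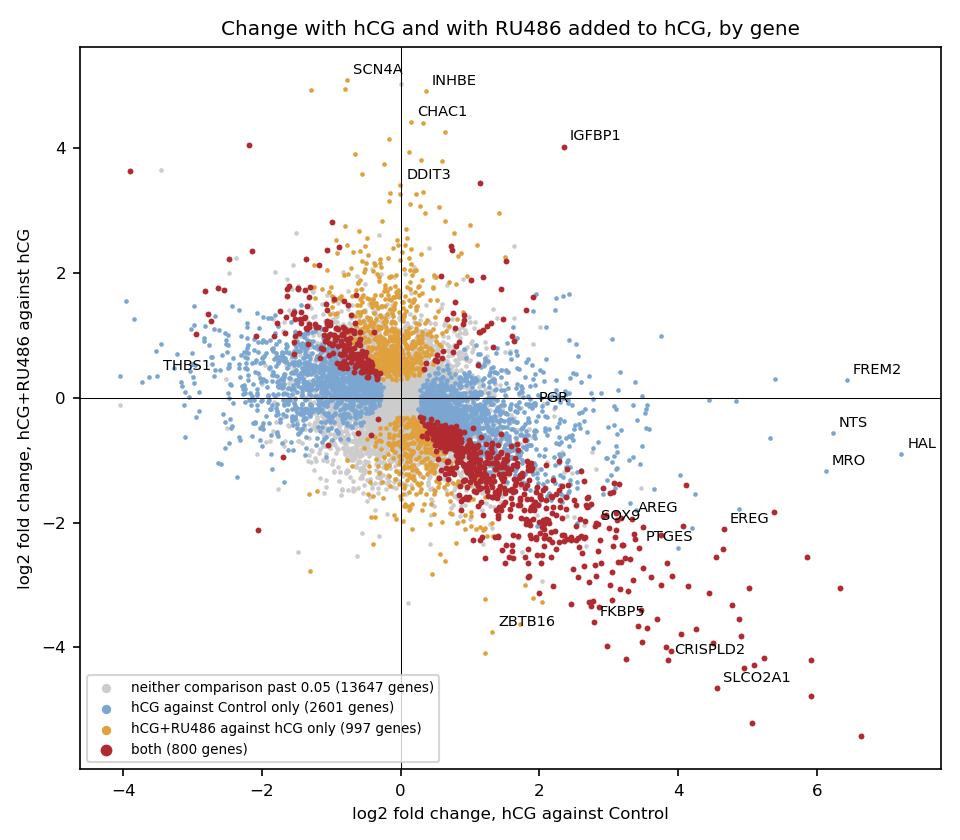
Log2 fold change with hCG (horizontal axis) against log2 fold change with RU486 added to hCG (vertical axis) for 18045 genes with a printable symbol, each point a gene, from the authors' deposited table. Of the 800 plotted genes past an adjusted p of 0.05 in both comparisons (red), 756 have opposite signs.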

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

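The test in this part was chosen after its result was seen. By the authors' deposited table, 8609 genes passed an adjusted p of 0.05 in the overall F test, and 3602 of them passed in none of the 3 comparisons. After the share of the 3 groups was subtracted, 7333 genes, or 40.6% of the table, passed 0.05 in the remainder. Both counts stand out because they are signals in columns that the 3 comparisons do not use. A candidate explanation is further groups in the authors' fit, or further terms, beside the 3 treatments. Its test was the numerator degrees of freedom of the overall F, which were 6 where 3 groups give 2, and the remainder was never negative, with a smallest value of 0.0055. What such terms would be is not given in the sources used here, and no biological explanation was tested. The p-values of the 3 comparisons follow a t distribution with the 21.923 denominator degrees of freedom of the overall F, with standard errors equal to within a ratio of 1.00028, so they share its estimate of the spread.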

How the results depend on the processing

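The alternatives with an adjusted p under 0.01, a joint adjustment, a minimum mean expression, centring, Spearman correlation, ranks or a correlation of 0.05 were chosen after seeing the data. No paired analysis was possible because the deposited table holds no value per library. For the same reason the replicate block, leaving out each replicate, other tests, normalizations, count filters, pseudocounts, fits of 2 groups, robust estimation, splitting the hCG libraries, an estimated correlation and fry were not run, nor were other splits of the samples counted. How far 1 library decides any call is therefore open, and depth cannot be weighed.

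Counts fell with stricter thresholds, which by construction call fewer genes. At 2-fold, 1683 genes changed with hCG, 934 with RU486 and 1475 against Control, and 394 moved back (341 raised and 53 lowered by hCG). Against a fold of 1.2 these were 1421, 721, 1215 and 280 (256 and 24). At an adjusted p under 0.01 they were 1612, 842, 1390 and 303 (263 and 40). Joint adjustment, either expression minimum and centring kept every count within 1.5 times. The Spearman correlation of -0.420 lay outside the bootstrap interval of Pearson's r, and the cause was not tested. Camera called 11, 8 and 9 lists for hCG, RU486 and hCG+RU486 against Control, then 11, 6 and 6 with a correlation of 0.05 and 11, 6 and 12 with ranks. Ranks also called lists that the main setting did not, namely dissociation stress for hCG, hypoxia for RU486, and dissociation stress, cAMP feedback and luteal identity against Control. Gene ontology calls fell from 28, 19 and 43 terms to 5, 1 and 10 with a correlation of 0.05, and to 19, 10 and 29 with ranks. Of 777 values for 259 named genes, 403 past the threshold, 69 lost the call at 2-fold, 110 against a fold of 1.2 and 121 at 0.01. These settings leave the fold changes as they are, so no direction could change.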

Other observations

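The tests on genes moved back were chosen after those results were seen, whereas those on stress genes used lists written after that pattern was seen and before their members were examined. Among 1349 gene ontology terms, camera called 13 higher and 6 lower with RU486 added to hCG, from statistics of the authors' deposited table. The term for tRNA aminoacylation was higher (32 genes, adjusted p 1.75e-07), as were amino acid transport (22 genes, adjusted p 0.0016) and translational initiation (121 genes, adjusted p 0.0016), and DNA replication was lower (109 genes, adjusted p 0.0029). Translational initiation was lower with hCG (adjusted p 0.00019), and ER to Golgi transport was higher (159 genes, adjusted p 0.017). With a preset correlation of 0.05 only tRNA aminoacylation of these calls was kept (adjusted p = 0.0054), and with ranks tRNA aminoacylation and amino acid transport were lost (adjusted p = 0.13 and 0.72). Some of the aminoacylation genes belong to the ATF4 list tested further on. In the authors' deposited table, 3 of 31 cytokine and chemokine genes rose with hCG, among them TNFSF11, the gene of RANK ligand, at 4.96 ± 0.50, which fell by 4.33 ± 0.50 with RU486.

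The authors' deposited table assigns genes to modules, which were built by the authors and are not independent evidence of direction. Of 1182 genes in the brown module, which holds PGR and SOX9, 782 were higher with hCG and 480 lower with RU486. In the turquoise module of 1687 genes 495 were higher with hCG, 336 higher with RU486 and 974 above Control with both. The pink module of 532 genes had 276 higher and 0 lower with RU486, against 11 higher and 61 lower with hCG.

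Of 3406 genes changed by hCG 757 moved back with RU486, and most had no call with it. Pearson's r of -0.474 was no more negative than the simulated -0.499. Changes with hCG that RU486 leaves in place pull r towards 0, so r cannot decide whether genes moved back. The shared hCG libraries alone would give a covariance of -0.056, outside the bootstrap interval of -0.240 to -0.210 around the measured -0.225. This covariance argues against them as the whole cause, although the interval resamples genes, which are not independent replicates. The same covariance argues against a scaling difference as the whole cause, since 1 factor shifts the log2 values of all genes alike and adds no covariance across them. Block of the glucocorticoid receptor in place of the progesterone receptor stays open, since the 21 progesterone receptor targets outside the glucocorticoid list had a median of -0.31 with a bootstrap interval from -1.23 to 0.20. RU486 blocks both receptors, so loss of progesterone receptor action may contribute but cannot be told apart from the other here.

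Part of the stress genes rose with RU486. A list of 30 ATF4 targets had a median log2 change of 1.89 (interval 1.63 to 2.19, camera adjusted p 2.43e-79), with 28 higher, 0 lower, and SLC7A5 and VLDLR not past the threshold. Noise of low genes is argued against for these targets, because 27 of the risen ones lie above the table's median expression. Most of the list lies above that median, so stress genes with low expression outside it are not covered. ATF4 activity is a hypothesis that the rise of these targets goes with, though it was not measured, while an NRF2 response stays open. A general endoplasmic reticulum stress response would raise chaperone and degradation genes as a set. The 20 chaperone and degradation genes had a median of 0.089 (interval up to 0.21, camera adjusted p 0.080) with 4 higher. That list left out 8 such genes seen before. HSPA5, XBP1 and HERPUD1 among them rose with RU486, by 1.18 ± 0.27, 1.33 ± 0.25 and 1.26 ± 0.23, and the other 5 did not pass the threshold. With these 8, picked after their values were seen, the 28 genes had the same median and an interval from 0.02 to 0.248. Among them 7 were higher, 0 lower and 21 without a call. The median of these 28 genes lies far below the 1.89 of the ATF4 targets, so they did not rise as those did. With 7 higher and 0 lower, an endoplasmic reticulum stress response stays open, be it general or limited to genes such as HSPA5, XBP1 and HERPUD1. Of the 20 genes 12 were higher with hCG (median 0.50) and 11 with both compounds against Control (median 0.69, camera adjusted p 1.2e-12). Since hCG without RU486 already raised them, the change between hCG+RU486 and hCG cannot decide this question. The 16 NRF2 targets had a median of 0.23 (interval 0.04 to 0.34), with 1 higher, 1 lower and 14 without a call (camera adjusted p 0.080), and HMOX1, which that list left out, rose by 2.56 ± 0.57. Without a labelled group given RU486 alone an action of the compound apart from hCG was not tested.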
